A study of Mus musculus with 6 samples.

How the data were processed

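RNA was measured by sequencing in white adipose tissue of mice, in 3 wild-type (WT) libraries and 3 libraries of the genotype labelled ++Oxtr. The series text places the tissue in the gonadal depot. The labels do not describe the construct behind the name ++Oxtr, so the groups are called by their labels. WT replicates carry the numbers 10, 11 and 12, and ++Oxtr replicates the numbers 7, 8 and 9. The groups were taken from the sample titles. Nothing in the labels says that the replicates are separate animals, so the p-values measure the spread between these samples, which may be technical.

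Total RNA was extracted with Trizol and made into libraries with a NEBNext Ultra II RNA kit, per the labels' protocols. The submitters' processing notes name mm10 as the genome build. The aligner, the counting program and the annotation release are not given in the sources used here, nor whether counting used strand. The deposited table has 21959 rows with a raw read count and an FPKM value for each library, per the file headers. The deposited FPKM equals the read count divided by the gene length and by the column sum of the counts, with a largest relative error of 5.1e-15. Of the gene identifiers, 21851 were found in GENCODE M21, 21723 of them as protein coding, and 51 rows had no symbol. Start and end of 514 rows matched GENCODE M21 on GRCm38, while 21394 rows had a gene span of the same size. The coordinates in the table are therefore on other positions than GRCm38, the assembly that mm10 names, so the stated build and the table conflict. All positions given here are those of GENCODE M21 on GRCm38. No strand setting is known, so reads of overlapping and antisense genes cannot be told apart.

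Total counts per library ran from 14314517 to 19186696. A count of 0 in a library allows up to 3 counts, which is 0.156 to 0.21 CPM at these depths. Such floors cover counting error only. In each pair of libraries of a group, counts differed by 19.1 to 54.4 times the sampling noise (chi-square over degrees of freedom), so no library was treated as a copy of another.

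The main test was the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3 on the deposited counts, with TMM factors, robust dispersion and genes kept by filterByExpr. It ran on 13566 genes with no covariates and Benjamini-Hochberg adjustment, at an adjusted p threshold of 0.05. CPM values are scaled with the TMM factors, and mean ± SD is over 3 libraries. Log2 fold changes are ++Oxtr over WT, with the standard error from the fit. For single genes and for the mean log2 level of lists an exact 2-sided permutation test over the 20 assignments of the libraries was added. Its smallest possible p is 0.1. DESeq2 1.42.0 and limma 3.58.1 were used as alternatives.

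Before the data were examined, 42 gene lists were written for pathways, cell types, neighbouring organs and signs of RNA quality. The 37 lists with at least 5 tested members entered camera with a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were the alternatives. Further lists were written after the data were seen, as were all tests on them. The named genes were fixed by rule: Oxtr, Ucp1, the 10 genes with the smallest unadjusted p in each direction that did not overlap between groups and had a mean of at least 1 CPM, and members of each list that passed (the 2 with the smallest p and the first member). The rule first asked for genes past the adjusted threshold, of which there were none. Some genes that the rule takes are not reported here. Other genes are named as chosen after their values were seen.

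The steps were tested on simulated counts for this comparison with 13566 genes and 200 of them changed. The edgeR test recovered 74% of the genes changed 2-fold and 92% of those changed 4-fold, with 14 calls among unchanged genes. DESeq2 recovered 79% and 97%, with 59 calls among unchanged genes. With no gene changed, edgeR called 4 genes and DESeq2 called 32. Camera called the list of 30 genes raised 1.3-fold and 0 of 9 unchanged lists, and 0 of 10 lists where no gene changed. The simulated genes were drawn independently of each other, so these runs do not test camera on lists with correlated members. The changed genes left out those of low mean count, and no simulated library carried a difference shared by many genes. The recovered shares therefore need not hold for these data. In the data the estimated correlation was 0.42 for the respiratory chain, 0.38 for the tricarboxylic acid cycle and 0.47 for the mitochondrially encoded list.

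Alternatives fixed before the data were examined were DESeq2, limma-voom with quality weights, DESeq2 size factors, upper quartile factors, no filter, a mean of at least 1 CPM, limma on log2 of the deposited FPKM plus 0.5, rows summed per symbol, other thresholds, and each library left out in turn. Added after seeing the data were a score of multiciliated epithelium genes as a covariate, a correction for gene length and GC content, limma on log2 CPM, and DESeq2 at an unadjusted p under 0.05 with a log2 fold change of at least 1 in size. The figures were drawn with matplotlib 3.10.9.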

Results

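The libraries held 16949393, 14314517 and 14713091 counts in WT replicates 10, 11 and 12, and 19186696, 15347059 and 15086909 in ++Oxtr replicates 7, 8 and 9. Between 15504 and 16013 genes had at least 1 read per library. The share of counts from mitochondrially encoded genes was 4.01%, 4.53% and 3.69% in WT and 5.07%, 5.05% and 5.49% in ++Oxtr. Correlations of log2 CPM between libraries ran from 0.941 to 0.984. The mean correlation of ++Oxtr replicate 7 was 0.958 with its own group and 0.979 with WT. It was 0.954 and 0.951 for ++Oxtr replicate 8, and 0.9613 and 0.9616 for ++Oxtr replicate 9. Each WT library had a higher mean correlation with its own group (0.974 to 0.976) than with ++Oxtr (0.959 to 0.970). The first principal component held 46.6% of the variance and set ++Oxtr replicate 8 (54.7), ++Oxtr replicate 9 (22.6) and WT replicate 12 (9.23) apart from the other libraries, at -33 to -24.2. The second held 21.2%, with ++Oxtr replicate 9 at 43.1.

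The design asks how the fat of ++Oxtr mice differs from that of WT mice in genes of adipose development and energy metabolism. Oxtr, the gene of the oxytocin receptor (ENSMUSG00000049112, GRCm38 chromosome 6, 112473683 to 112489943, minus strand, protein coding), was at 42.8 ± 19.8 CPM (SD, n = 3) in WT and 87.4 ± 4.87 CPM (SD, n = 3) in ++Oxtr. The WT libraries were at 22, 61.4 and 45.2 CPM and the ++Oxtr libraries at 90.7, 89.7 and 81.8 CPM, so the groups did not overlap. The fitted log2 fold change was 1.03 (SE 0.34), with an adjusted p of 0.469 by edgeR and 0.0573 by DESeq2. The exact permutation p was 0.1, the smallest that 3 against 3 libraries allow. DESeq2 gave adjusted p of 0.00924 without WT replicate 10 and 0.00145 without WT replicate 11, and of 0.243, 0.185, 0.227 and 0.502 without WT replicate 12 and ++Oxtr replicates 7, 8 and 9.

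Ucp1, the uncoupling protein of brown and beige adipocytes (GRCm38 chromosome 8, 83290352 to 83298452), had 5, 1 and 4 reads in WT and 56, 7 and 4 reads in ++Oxtr replicates 7, 8 and 9. A single library thus held most of its reads. The gene did not pass the filter on low counts. Without the filter its log2 fold change was 2.52 (SE 1.03), with an edgeR adjusted p of 0.617. DESeq2 without a filter gave 2.56, at an unadjusted p of 0.0233 and an adjusted p of 0.39.

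**Figure D1:**
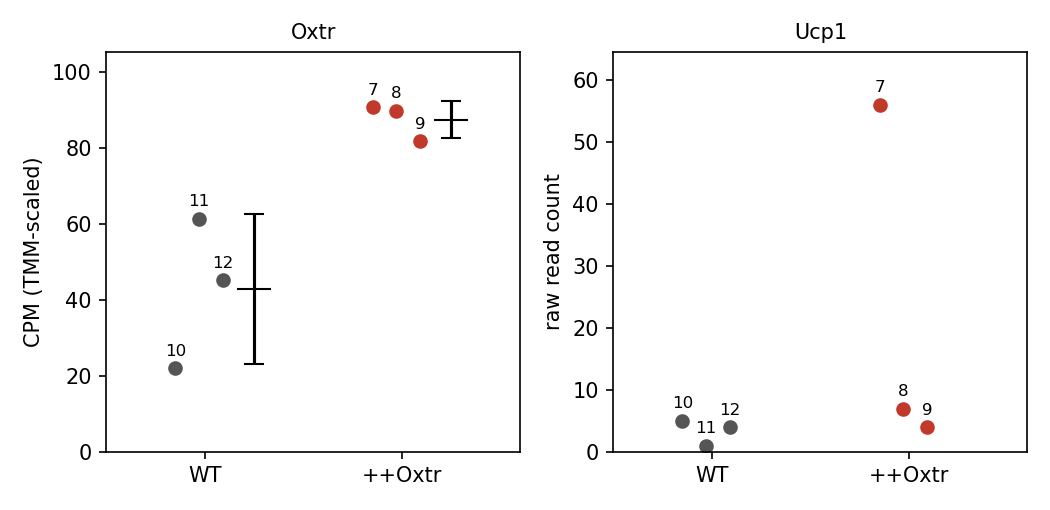
Oxtr in CPM scaled with TMM factors (left) and Ucp1 in raw read counts (right), one point per library with its replicate number; the bars for Oxtr are the mean ± SD of 3 libraries. The ++Oxtr libraries sit at 81.8 to 90.7 CPM of Oxtr, above the WT libraries at 22 to 61.4, and ++Oxtr replicate 7 alone has more than 10 reads of Ucp1, at 56.

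Of the genes with the smallest p at higher values in ++Oxtr, Pygl, a glycogen phosphorylase, was at 292.6 ± 29.6 CPM in WT and 552.3 ± 49.0 in ++Oxtr (SD, n = 3). Fabp5, a fatty acid binding protein, was at 189 ± 9.0 and 396.2 ± 74.0 CPM. Mgst2, a microsomal glutathione transferase, was 1.09 higher on the log2 scale (SE 0.12), Lipg, endothelial lipase, 1.33 higher (SE 0.20), and Nat8l, which makes N-acetylaspartate, 0.79 higher (SE 0.12). The potassium channel gene Kcnk3 was 0.84 higher (SE 0.12), and Syne3, Acsf2, Clmp and Met were 1.14, 0.96, 1.04 and 0.78 higher.

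Of the genes with the smallest p at lower values in ++Oxtr, the log2 fold change was -0.94 (SE 0.11) for Egfr, the epidermal growth factor receptor, -0.67 (SE 0.08) for Stim1, a calcium sensor of the endoplasmic reticulum, and -0.66 (SE 0.09) for Gas6, a ligand of TAM receptors. Sult1e1, estrogen sulfotransferase, was at 113 ± 9.4 CPM in WT and 38.4 ± 11.6 in ++Oxtr (SD, n = 3). Prtn3, Trp53inp2, Adap2, Scara5 and Gnb4 had log2 fold changes of -1.71, -1.17, -0.94, -0.81 and -0.73.

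By edgeR 0 of 13566 genes passed an adjusted p of 0.05, and the smallest adjusted p was 0.121, shared by 13 genes. At an unadjusted p under 0.05, edgeR gave 603 higher and 606 lower genes. DESeq2 on the same genes passed 94 higher and 96 lower genes at an adjusted p of 0.05, among them all the genes named above by smallest p, and limma-voom with quality weights passed 0. DESeq2's adjusted count was 52 higher and 61 lower without WT replicate 12, 147 higher without ++Oxtr replicate 7, 58 lower without WT replicate 11 and 60 lower without ++Oxtr replicate 8. The groups did not overlap in 2042 genes, 15.1% of those tested, where chance gives 10% on average over all splits of the libraries. Genes measured in the same libraries move together, so any single split can lie above or below that average. Whether other splits reach such a share was not tested.

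The series text states 365 differential genes, 286 higher and 79 lower, with no test. DESeq2 without a filter, at an unadjusted p under 0.05 and a log2 fold change of at least 1 in size, gave 286 higher and 79 lower genes, the same numbers. This combination was found after more than 10 combinations of tool, filter and threshold had been tried on these data, and whether the genes are the same is not known. An unadjusted threshold does not control the number of false calls among 21959 rows. Ucp1, with most of its reads in ++Oxtr replicate 7, was among the 286 higher genes. Without ++Oxtr replicate 8 the count was 166 higher and 95 lower, with 102 of the 286 higher genes kept. It was 538 higher without ++Oxtr replicate 7, 177 higher without ++Oxtr replicate 9, and 172 higher and 52 lower without WT replicate 11.

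Genes of mitochondrial energy metabolism lay together at higher values in ++Oxtr. Of 39 tested nuclear-encoded genes of the respiratory chain, 37 were on the higher side, with a median log2 fold change of 0.30 (camera adjusted p = 1.15e-18). All 23 tested genes of the tricarboxylic acid cycle were on the higher side, with a median of 0.33 (camera adjusted p = 1.81e-17). So were all 12 tested mitochondrially encoded genes, with a median of 0.41 (camera adjusted p = 2.36e-09). With an estimated correlation these calls were lost, at adjusted p = 0.315, 0.303 and 0.315. The number of members past edgeR adjusted over all genes was 0 in each list; adjusted over the list alone it was 24, 14 and 1. Pdha1, a subunit of pyruvate dehydrogenase, was at 359.7 ± 58.3 CPM in WT and 660.7 ± 117.2 in ++Oxtr (SD, n = 3). Cs, citrate synthase, was 0.33 higher on the log2 scale (SE 0.12), and the succinate dehydrogenase genes Sdhd and Sdhb were 0.38 (SE 0.09) and 0.40 (SE 0.09) higher. Ndufa1 was 0.22 higher (SE 0.13). Of mitochondrially encoded genes, mt-Co1 was 0.49 higher (SE 0.15), mt-Nd1 0.35 (SE 0.19) and mt-Co3 1.29 (SE 0.30). In WT mt-Co3 was at 19.1 CPM and mt-Co1 at 17420 CPM.

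Fatty acid oxidation genes and thermogenic genes were also higher as lists. Of 24 tested genes of fatty acid oxidation, 22 were on the higher side, with a median of 0.24 (camera adjusted p = 7.26e-08). This was the only list of the 37 past fry (adjusted p = 0.0173), while it had an adjusted p = 0.138 with an estimated correlation. Adjusted over the list alone 5 members passed, against 0 over all genes. Hadhb and Acadl, enzymes of the mitochondrial pathway, were 0.38 (SE 0.09) and 0.42 (SE 0.10) higher, while Cpt1a, which admits long-chain fatty acids to mitochondria, had a log2 fold change of -0.22 (SE 0.10). Of 22 tested thermogenic and brown or beige adipocyte genes, 20 were on the higher side, with a median of 0.54 (camera adjusted p = 2.20e-08; adjusted p = 0.303 with an estimated correlation). Adjusted over the list alone 3 members passed, against 0 over all genes. With a multiciliated epithelium score as a covariate, chosen after seeing the data, the median was 0.32 and the list still passed camera. Slc36a2, an amino acid transporter used as a brown adipocyte marker, was at 160.5 ± 17.8 CPM in WT and 275.5 ± 39.9 in ++Oxtr (SD, n = 3).

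**Figure D2:**
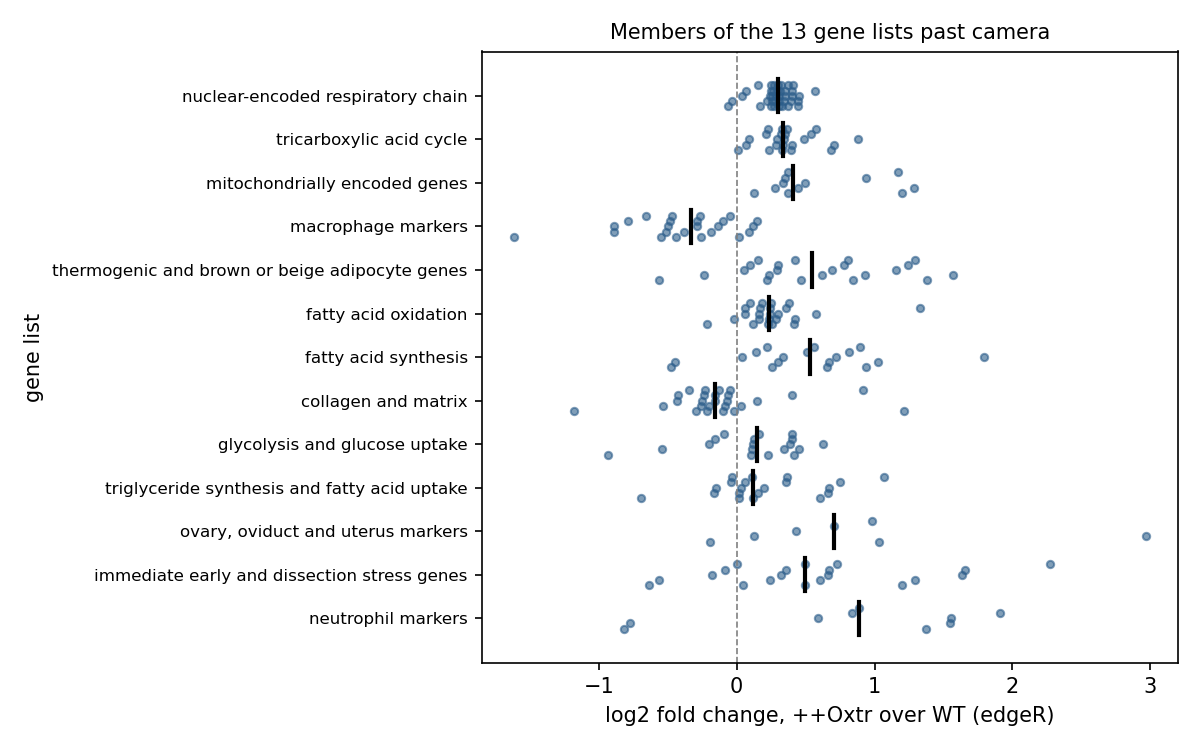
Log2 fold change (edgeR, ++Oxtr over WT) of each tested member of the 13 gene lists past camera with a preset correlation; each point is a gene and the black line is the median of the list. The respiratory chain genes cluster around a median of 0.30 and the macrophage markers around -0.33.

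Genes of fat and sugar metabolism were also higher as lists. Of 18 tested fatty acid synthesis genes, 16 were on the higher side, with a median of 0.53 (camera adjusted p = 7.19e-07; adjusted p = 0.589 with an estimated correlation). The groups overlapped in the mean log2 level of the list around its average, at -0.83, 0.08 and -0.01 in WT replicates 10, 11 and 12 and 0.01, 0.70 and 0.04 in ++Oxtr replicates 7, 8 and 9 (exact permutation p = 0.4). The median was 0.32 without WT replicate 10, 0.26 without ++Oxtr replicate 8 and 0.28 with a multiciliated epithelium score as a covariate, chosen after seeing the data, and the list still passed camera. Adjusted over the list alone 4 passed, against 0 over all genes. Acaca, acetyl-CoA carboxylase, was 0.94 higher (SE 0.26), Me1, malic enzyme, 1.02 (SE 0.29), and Fasn, fatty acid synthase, 0.89 (SE 0.41). Of 18 glycolysis and glucose uptake genes 13 were on the higher side, with a median of 0.15 (camera adjusted p = 0.00788; adjusted p = 0.659 with an estimated correlation), and 4 passed adjusted over the list alone, against 0 over all genes. Pgk1 and Aldoa were 0.41 (SE 0.09) and 0.45 (SE 0.12) higher, and Slc2a1 0.11 (SE 0.15). The 5 members on the lower side included Gapdh at -0.93 and Pfkfb3 at -0.54, named after their values were seen. This call was lost without ++Oxtr replicate 8 (median 0.04, adjusted p = 0.137), ++Oxtr replicate 7 (0.0724) or WT replicate 10 (0.165), and the median was 0.27 without WT replicate 11, 0.24 without ++Oxtr replicate 9 and 0.10 with the covariate. Of 20 genes of triglyceride synthesis and fatty acid uptake 15 were on the higher side, with a median of 0.12 (camera adjusted p = 0.00788; adjusted p = 0.303 with an estimated correlation), and 1 passed adjusted over the list alone, against 0 over all genes. Gpam and Dgat1 were 0.67 (SE 0.20) and 0.36 (SE 0.13) higher. The median was 0.23 without WT replicate 11 and 0.18 with the covariate, and the call was lost without WT replicate 12 (median 0.08, adjusted p = 0.0885) and with limma on log2 CPM, chosen after seeing the data (adjusted p = 0.061).

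Macrophage markers were lower as a list. Of 24 tested markers 20 were on the lower side, with a median of -0.33 (camera adjusted p = 3.42e-09; adjusted p = 0.315 with an estimated correlation), and 5 passed adjusted over the list alone, against 0 over all genes. Cd163, a scavenger receptor, was at 101 ± 22.7 CPM in WT and 54.4 ± 10.4 in ++Oxtr (SD, n = 3), C1qa at 197.5 ± 18.8 and 145.4 ± 9.27, and Adgre1 at 101.3 ± 27.8 and 72.3 ± 16.3. Without ++Oxtr replicate 8 the macrophage median was -0.22 and the list still passed camera. Collagen and matrix genes were lower in 21 of 26, with a median of -0.16 (camera adjusted p = 0.0035; adjusted p = 0.568 with an estimated correlation), and 2 passed adjusted over the list alone, against 0 over all genes. Col5a2 and Fn1 had log2 fold changes of -0.43 (SE 0.09) and -0.54 (SE 0.12), and Col1a1 of 0.03 (SE 0.25). The median was -0.10 without WT replicate 11, and the collagen call was lost without ++Oxtr replicate 8 (median -0.077, adjusted p = 0.137) and with a multiciliated epithelium score as a covariate, chosen after seeing the data (median -0.095, adjusted p = 0.149).

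The last lists past camera were higher in some of the ++Oxtr libraries. Immediate early and dissection stress genes were on the higher side in 16 of 20, with a median of 0.49 (camera adjusted p = 0.00815; adjusted p = 0.897 with an estimated correlation). Egr1 was at 100, 26.6 and 144.4 CPM in ++Oxtr replicates 7, 8 and 9, against 29.1 ± 7.23 CPM in WT (SD, n = 3). Fosb and Fos were 2.27 (SE 0.85) and 0.73 (SE 0.61) higher on the log2 scale. The call was lost without ++Oxtr replicate 9 (median 0.09, adjusted p = 0.915), ++Oxtr replicate 7 (0.0816) or WT replicate 11 (0.307). Neutrophil markers were on the higher side in 7 of 9, with a median of 0.88 (camera adjusted p = 0.0131; adjusted p = 0.589 with an estimated correlation). S100a9, Retnlg and S100a8 were 1.91 (SE 0.62), 1.55 (SE 0.48) and 1.37 (SE 0.56) higher. The 2 members on the lower side were Camp at -0.82 and Mmp9 at -0.77, named after their values were seen. The neutrophil call was lost without ++Oxtr replicate 9 (median 0.57, adjusted p = 0.291) or WT replicate 11 (0.231). Markers of ovary, oviduct and uterus were on the higher side in 6 of 7, with a median of 0.71 (camera adjusted p = 0.00788; adjusted p = 0.589 with an estimated correlation), lost without ++Oxtr replicate 8 (median 0.41, adjusted p = 0.162). With a multiciliated epithelium score as a covariate, chosen after seeing the data, the median was 0.26 and the call was lost (adjusted p = 0.159). Their members with the smallest p were Esr1, the estrogen receptor, at 77.9 ± 9.41 CPM in WT and 153.8 ± 43.5 in ++Oxtr (SD, n = 3), and Pax8, at 5.40 CPM in ++Oxtr replicate 8 and at most 1.22 in the other libraries. Ovgp1 was 0.43 higher (SE 0.47). The testis germ cell and vas deferens list had 4 tested members, too few for camera, all on the higher side. In mean log2 level, ++Oxtr replicate 8 was the highest library in the ovary (1.083), testis (1.098) and mammary epithelium (1.262) lists. The 4 tested sex-linked genes ran from -0.142 to 0.12 over the libraries on that scale. Esr1 was at 67.2 CPM or more in each library. Which tissue these markers came from was not tested. Adjusted over the list alone the immediate early and neutrophil lists had 0 members past edgeR and the ovary list 1, against 0 over all genes.

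Other lists did not pass. The median was -0.0045 for 24 pan-adipocyte genes, -0.0042 for 20 lipolysis genes and -0.06 for 27 oxytocin signalling genes, with camera adjusted p of 0.609, 0.891 and 0.802. Endothelial markers had a median of -0.09 and T and natural killer cell markers one of 0.32, with camera adjusted p of 0.137 and 0.355. In mean log2 level around its average, the T and natural killer list was at 1.19 in ++Oxtr replicate 9. It was at -0.48 and -0.44 in ++Oxtr replicates 7 and 8, and at -0.05, 0.11 and -0.32 in WT replicates 10, 11 and 12. Only ++Oxtr replicate 9 thus lay above the WT libraries.

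Genes of multiciliated epithelium, a list of 30 written after the data were seen, differed between libraries of the same group. Their summed level was 12, 12.6 and 49.6 CPM in WT replicates 10, 11 and 12, and 12.1, 274.9 and 61.4 CPM in ++Oxtr replicates 7, 8 and 9. Foxj1, a regulator of motile cilia chosen after its values were seen, was at 29.2 CPM in ++Oxtr replicate 8, 6.55 in ++Oxtr replicate 9 and 5.90 in WT replicate 12, and at most 0.14 in the others.

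**Figure D3:**
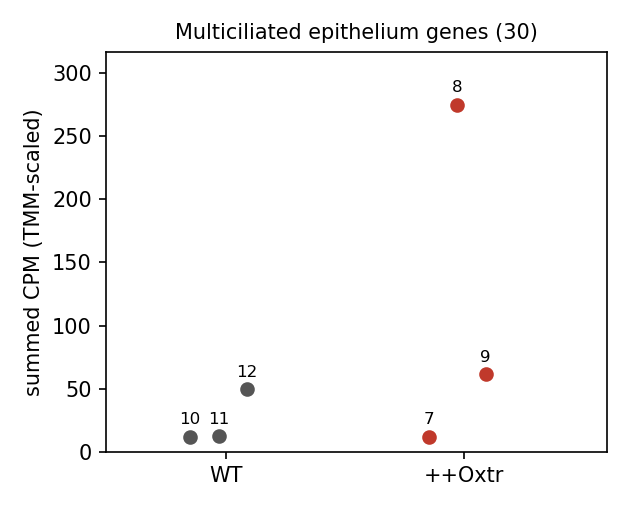
Summed level of 30 multiciliated epithelium genes in CPM scaled with TMM factors, one point per library with its replicate number. ++Oxtr replicate 8 sits at 274.9 CPM, ++Oxtr replicate 9 and WT replicate 12 at 61.4 and 49.6, and the remaining libraries at 12 to 12.6.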

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

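The covariate, the DESeq2 counts at an unadjusted p, the length and GC correction and limma on log2 CPM were chosen after seeing the data. No paired analysis was possible because the groups share no replicate numbers. With edgeR, the count of 0 genes past an adjusted p of 0.05 held under both other normalizations, both other filters, rows summed per symbol, an adjusted p of 0.1, the covariate and each library left out, and also with limma-voom and limma on FPKM, against 603 higher and 606 lower at an unadjusted p under 0.05. DESeq2 gave 94 higher and 96 lower. An unadjusted edgeR p under 0.05 with a log2 fold change of at least 1 in size gave 113 and 72, and that threshold in DESeq2 without a filter gave 286 and 79. The 286 became 182 among genes kept by the filter, 107 with the multiciliated covariate and 166 to 538 with a library left out, and the 79 became 52 to 117. DESeq2's adjusted counts ran over 52 to 147 higher and 58 to 132 lower. Of gene lists, 11 were higher and 2 lower by camera, against 0 and 0 with an estimated correlation, and 1 and 0 by fry, both of which allow for correlation between members. The 2 lower lists became 4 with upper quartile factors, 4 with limma on log2 CPM, 5 with the covariate and 1 to 6 with a library left out, and the cause was not tested. The Oxtr log2 fold change kept its sign and stayed short of an adjusted p of 0.05 in each edgeR and limma alternative and in DESeq2 on all 6 libraries, at 0.72 to 1.39 with a library left out. Signs turned in genes that did not pass: Col1a1 at -0.19 with limma-voom, -0.067 on FPKM and -0.32 to 0.18 with a library left out, and Slc2a1 at -0.039 with the covariate. The cause was not tested. Among named genes, 39 values passed under DESeq2 that had not passed under edgeR. The planned pseudocounts of 0.1 and 1 were not run, since the table holds counts. Depth limits genes such as Ucp1, at 1 to 56 reads.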

Other observations

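All tests on the added lists and on pathways, the tests of ciliated epithelium on gene counts, of the share of adipocytes, of stromal cells and of splits on the edgeR count and the DESeq2 unadjusted count were chosen only after the results were seen. Pathways in the deposited annotation with 10 to 300 tested genes numbered 238. Camera passed 21 higher and 4 lower, and 0 with an estimated correlation. Oxidative phosphorylation had 92 of 110 genes on the higher side (median 0.25), propanoate metabolism 27 of 29 (0.22) and complement and coagulation cascades 36 of 52 on the lower side (-0.21), each at an adjusted p = 0.482 with an estimated correlation. Of the added lists, branched-chain amino acid breakdown was on the higher side in 15 of 16 (median 0.20, camera adjusted p = 0.000221), the mitochondrial ribosome in 25 of 30 (0.11, 0.00189) and the pentose phosphate pathway in 6 of 8 (0.17, 0.0123), each at an adjusted p = 0.387 with an estimated correlation. The glucocorticoid-responsive genes had a median of -0.15 (camera adjusted p = 0.014; adjusted p = 0.416 with an estimated correlation), with 8 of 17 on the higher side. All 23 tested multiciliated genes were on the higher side (median 2.57, camera adjusted p = 1.18e-05), as were all 10 tested genes of general epithelium (1.52, 0.00629), each at an adjusted p = 0.393 with an estimated correlation. Of the 30 multiciliated genes, 15 had at most 3 counts over WT replicates 10 and 11 and ++Oxtr replicate 7 together.

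The genes in this paragraph were chosen after their values were seen. The complement gene C6 was at 74.6 ± 37.7 CPM in WT and 10.4 ± 1.76 in ++Oxtr (SD, n = 3), with an adjusted p of 0.16 by edgeR and 4.64e-14 by DESeq2. Fkbp5, a glucocorticoid-induced chaperone, was at 383.8 ± 96.3 and 122.6 ± 53.8 CPM, and Emp1 at 639.9 ± 128.1 and 230.1 ± 93.9. Tkt, transketolase, was at 1082 ± 340.4 and 2395 ± 505.5 CPM. The adjusted p of Fkbp5, Emp1 and Tkt was 0.347, 0.347 and 0.349 by edgeR and 1.58e-05, 9.48e-05 and 0.00129 by DESeq2. The adipokine gene Lep was at 502.5 ± 247.8 and 223.7 ± 150.3 CPM, and the groups overlapped, with an adjusted p of 0.662 by edgeR and 0.76 by DESeq2.

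The first pattern is the excess of higher over lower genes, 286 against 79, at an unadjusted DESeq2 p. A candidate explanation is ciliated epithelium carried over into some fat pads, since 45.1% of the higher genes (95% exact binomial interval 39.2% to 51.1%) had their highest value in ++Oxtr replicate 8 and in WT replicate 12, the libraries with the highest multiciliated level in each group, against 12.1% of other genes with a read and 19.9% of other genes of like mean count. The interval includes the 50% set, after seeing the data, for the explanation to account for the excess. It treats the genes as independent, though they come from the same 6 libraries and would move together if they shared a tissue. The interval therefore does not measure the spread between libraries and cannot decide this. Whether the explanation accounts for all or part of the excess stays open. With the multiciliated score as a covariate the count was 107 higher and 98 lower, with 91 of the 286 kept. The epithelial genes Epcam, Cldn2 and Cuzd1, chosen after their values were seen, were at 30.3, 43.8 and 49.2 CPM in ++Oxtr replicate 8, 3.85, 8.03 and 3.78 in ++Oxtr replicate 9 and 4.39, 6.55 and 8.26 in WT replicate 12, and at most 0.41 in the others. Of the 10 splits of the 6 libraries, 2 gave at least as many genes, the real one included, with 365 in the real split and 671 in the split of WT replicates 10 and 11 and ++Oxtr replicate 7 from the others, the libraries with the lowest multiciliated level, and 10 splits are too few for a share under 0.05, and an effect of the genotype also stays open, untested.

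The second pattern is the higher level of mitochondrial and oxidative lists. Ciliated epithelium as the whole cause was argued against by the respiratory chain median, 0.328 with the multiciliated score as a covariate and 0.303 without it, and a trend with gene length or GC content by the median of 0.245 after correction, where the list still passed camera with the preset correlation (adjusted p = 5.98e-13). Without correction the call was lost with an estimated correlation (adjusted p = 0.315). By the rule set for it, a larger share of adipocytes cannot be told apart. The pan-adipocyte median of -0.0045 lay below the respiratory chain median by less than the spread of single members (SD 0.362). That spread exceeds the respiratory chain median itself, so even an unchanged pan-adipocyte list would have left the question open. Of the 24 pan-adipocyte genes, 10 were on the higher side (camera adjusted p = 0.609). They thus showed no rise shared by adipocyte genes in general. Of the 10 splits, 8 gave at least 13 lists, the real one with 13 included, and the highest other gave 20. That count takes lists of any kind in either direction, so it does not rank the splits for this pattern. In mean log2 level the groups did not overlap for the respiratory chain, tricarboxylic acid cycle and mitochondrially encoded lists. Nor did they for the fatty acid oxidation and thermogenic lists. The exact permutation p was 0.1 for each, the smallest possible. These 10 splits are too few for a share under 0.05, and an effect of the genotype stays open, untested.

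The third pattern is the lower level of macrophage markers. By the rule set for it, a lower share of all stromal and vascular cells cannot be told apart from it. The median of 55 endothelial, progenitor and pericyte markers was -0.055, above the macrophage median of -0.335. The gap was less than the spread of single markers (SD 0.288), which is not the error of a median. The endothelial, progenitor and pericyte lists had medians of -0.087, -0.059 and -0.0088, and none passed camera (adjusted p = 0.137, 0.238 and 0.802). As lists these markers thus lay less far below WT than the macrophage markers, and a smaller shared fall stays open. For single genes, the real split gave 190 genes past DESeq2's adjusted threshold, 1 of the 10 splits, the real one, gave as many, and the highest of the others gave 189. That other split set WT replicates 10 and 11 and ++Oxtr replicate 7, the libraries with the lowest multiciliated level, apart from the rest. The real split was thus hardly ahead of it. By edgeR the real split and each of the other splits gave 0 genes, which is all 10, so that count cannot rank the splits; at an unadjusted p under 0.05 edgeR gave 1209 genes in the real split and 228 to 1064 in the others. These splits are too few for a share under 0.05.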
